A study of Homo sapiens with 6 samples.

How the data were processed

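Human aortic endothelial cells (HAECs), primary cells of the inner lining of the aorta, were cultured with no added glucose or with 125 or 250 mg/dL of added D-glucose, and 2 libraries were made per group, 6 in all. The labels' protocols give 48 h of exposure, a medium change and a further 24 h, 72 h in total, while the series' design text gives 24 h, so the duration is open. DNA methylation was measured by reduced-representation bisulfite sequencing, which reads cytosines near restriction sites and so favours CpG-rich DNA. The labels speak of duplicates and do not say how separate the cultures were, so the spread between these libraries may be technical. The limma p-values given below rest on that spread. The binomial, sign-flip and Fisher tests take clusters or genes as their units and do not measure it.

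Per the submitters' processing notes, the tools were FastQC 0.11.7, Trim Galore 0.4.4 and Bismark 0.20.0, with the builds hg38 and GRCh38.p12 named; the differential test is not given in the sources used here. The deposited table held 2605 entries for 2051 distinct tiles of 500 bp, since a tile was repeated for each gene annotated to it. Per the file headers, the authors gave each tile a methylation level in percent for each of the 6 libraries. The authors also deposited 1 p-value and 1 q-value per tile, and every q-value was under 0.05. Their headers name no groups, and both values are taken here to cover all 3 groups together. The authors' difference in percentage points carried no sign. Tested against every possible weighting of the libraries, it could be the largest of the 3 pairwise group differences in every tile, whereas 877, 86 and 801 tiles ruled out 125 mg/dL against control, 250 mg/dL against control and 250 against 125 mg/dL. The name of the table speaks of cytosines, but its units are tiles.

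Read counts and coverage were not used here, so the depth behind each value is unknown and no interval based on reads is given. Tiles that did not reach the authors' threshold were not analysed here. The ratio of q-value times rank to p-value lay between 96732 and 98516, which would be the number of tiles tested, times any estimated share of unchanged tiles, if the q-values came from a step-up procedure. Because the tiles were chosen for a difference among these same libraries, tests on them are not independent evidence that methylation differs, and adjusted p-values over them are not calibrated for the genome. No enrichment against the genome could be computed.

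The tests had been planned for separate lists of cytosines per dose with read counts. The table held neither, so group means of percent values and limma took their place, chosen after the unit was seen. Group values are unweighted means of 2 libraries ± SD (n = 2), and differences are dose minus control in percentage points. A tile was called outside the control range when both libraries of a dose lay above, or both below, both controls. Chance gives this in 33.3% of tiles for 2 exchangeable libraries against 2, before any selection of tiles for a difference. No exact test of 1 tile with 2 libraries against 2 can give a two-sided p below 0.333. limma 3.58.1 in R 4.3.3 was fitted to the percent values of all 6 libraries with 3 groups and a trend of the spread with the mean level, and was adjusted by Benjamini-Hochberg over 2051 tiles for each dose. Tested on simulated data with 200 changed tiles of 2051 for 250 mg/dL against control, limma recovered 0% of changes of 5, 10 or 20 points and 67% of changes of 40 points. A low number of limma calls is therefore no evidence that tiles were unchanged.

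Tiles with gaps of at most 1000 bp were joined into 2001 clusters, on which higher and lower means were compared by a two-sided exact binomial test. The size of the difference at 250 mg/dL was set against that at 125 mg/dL by a two-sided sign-flip permutation test with 100000 resamples. These tests treat clusters as independent although all clusters share the same 6 libraries. Both doses share the controls, so 100 draws of unchanged groups against common controls were simulated with the observed replicate spread. A further 20 draws kept the 2051 most different of 97000 simulated tiles. Genomic classes and 16 gene lists were compared between directions and doses by Fisher's exact test with Benjamini-Hochberg adjustment, 30 and 48 tests in all.

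The gene lists and the naming rule were fixed before the data were examined, and the rule, written for cytosines listed per dose, was fitted to tiles afterwards. The rule named, at each dose, the 10 genes with most tiles, the 5 largest gains and losses and the 5 clusters with most tiles in 1 direction, then the 5 largest differences found at both doses, every member of the endothelin and nitric oxide lists, and up to 4 members of every other list by smallest q-value. It gave 148 tiles, of which the text describes a part. Gene symbols are those of the deposited table; 2158 of 2199 were matched in a RefSeq gene table. By its positions, 578 of 2604 gene entries (22.2%) lay over 5 kb from the gene they were given to, at a median of 97.3 kb, and this is stated where such a gene is named. Coordinates, in hg38, and feature labels such as promoter are those of the deposited table. The feature labels name no gene or transcript, and 109 of the 578 distant entries carried a promoter label.

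Alternatives fixed beforehand were a q-value under 0.01, a difference of at least 25 points, autosomes, other cluster gaps and sizes, other votes in the gene lists, each library left out and the replicate number as a block. Chosen after seeing the data were limma on logit and arcsine square root scales, without the trend and on autosomes, limma adjusted over each list alone, sets of single libraries, split controls, the counts of fully separated groups and every test of a technical explanation. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.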

Results

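Methylation levels of 2051 tiles of 500 bp were compared among HAECs grown without added glucose and with 125 or 250 mg/dL of added glucose, with 2 libraries per group. The authors' q-values of these tiles ran from 3.14e-36 to just under 0.05, and 949 were under 0.01. The authors' difference had a median of 8.75 percentage points and a range of 0.157 to 73.6 points. It reached 25 points in 136 tiles and stayed under 5 points in 618. The number of reads behind each level is unknown.

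The listed tiles lay mostly in and around genes. An exon, intron or untranslated region was overlapped by 1577 tiles (76.9%), a promoter by 940 (45.8%) and a CpG island by 1201 (58.6%). Tiles in CpG islands had a median control level of 9.26%, and the 556 tiles outside islands, shores and shelves had one of 68.2%. The median size of the difference at 250 mg/dL was 5.10 points in islands and 11.9 points outside islands, shores and shelves. None of the 30 comparisons of genomic classes between directions or doses passed adjustment (Fisher's exact test, smallest adjusted p = 0.142, 2 with an unadjusted p under 0.05). These shares describe the list alone, since the tiles tested but not listed were not analysed here.

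The first comparison asked how methylation at 125 mg/dL stood against control. Of the tiles, 873 had a higher mean and 1169 a lower mean than control, with 9 equal, and the median size of the difference was 3.65 points. The largest loss among gene-annotated tiles was at a FOXL1 tile (chr16:87185001-87185500, over 5 kb from that forkhead gene), with a difference of -52.5 points. Inside BCR, which encodes a GTPase regulator, the tile at chr22:23290501-23291000 overlapped an exon and an intron and had a difference of -48.8 points. Its control libraries stood at 78.1% and 33.7% and its 125 mg/dL libraries at 4.76% and 9.52%, and without control replicate 1 the difference was -26.5 points. The TADA3 and ARPC4 tile at chr3:9788501-9789000, in a promoter and intron, stood at 45.5% and 42.1% in control and at 85.7% and 84.6% at 125 mg/dL, a difference of 41.4 points.

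Both 125 mg/dL libraries lay above both controls in 406 tiles and below both in 598, together 49.0% of tiles. Exchangeable libraries would give 33.3%, a value that leaves out the selection of tiles for a difference, so the excess alone is no evidence of a dose effect. Over clusters, 851 were higher and 1141 lower (42.7% higher, two-sided exact binomial p = 8.79e-11), while control replicate 1 lay above control replicate 2 in 51.2% of tiles. Among tiles with an authors' difference of at least 25 points the imbalance was not significant (63 clusters higher and 72 lower, 46.7% higher, exact binomial p = 0.491). So few clusters leave open whether it changed. limma called 0 tiles at 125 mg/dL, with 168 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0733; on the logit scale it called 3 and on the arcsine square root scale 2.

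At 250 mg/dL the differences from control were larger. Of the tiles, 922 had a higher and 1129 a lower mean, and the median size was 8.09 points. The tile in STXBP2, a regulator of vesicle fusion, which also lies within 5 kb of PCP2 (chr19:7637501-7638000, promoter and intron), rose from 23.6% in control by 73.8 ± 6.08 points (SE, n = 2 per group, limma adjusted p = 0.0489). Its 250 mg/dL libraries stood at 100% and 94.7% and its 125 mg/dL libraries at 40% and 43.5%. An intronic tile given to HMX2, a homeobox gene over 5 kb away, at chr10:123467501-123468000 rose by 24.0 ± 2.19 points. A tile without an annotated exon, intron or promoter, at chr16:24523001-24523500, was given to PRKCB, a protein kinase C gene over 5 kb away. It rose by 23.1 ± 2.16 points (SE, limma adjusted p = 0.0489 for both).

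Those 3 tiles were all that limma called at 250 mg/dL, with 535 at an unadjusted p under 0.05. With the replicate number as a block it called 0 tiles. HMX2 fell outside the naming rule and was chosen after its values were seen. In the HMX2 and PRKCB tiles all 4 glucose libraries stood at 100%, so the estimate at 125 mg/dL was the same and missed the threshold at an adjusted p of 0.0733 in limma. The controls stood at 75.7% and 76.3% for HMX2 and at 76.9% in both libraries for PRKCB. Replicates of the PRKCB tile thus had an SD of 0, and its SE came only from the spread that limma borrows from other tiles. The depth behind these values is unknown. No tile was called without control replicate 1, either 125 mg/dL replicate or 250 mg/dL replicate 1; without control replicate 2, 3 tiles were called, all lower, and without 250 mg/dL replicate 2, 128 were called.

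Both 250 mg/dL libraries lay above both controls in 720 tiles and below both in 890, together 78.5% of tiles. Exchangeable libraries would give 33.3%, again without the selection of tiles for a difference, so the excess alone is no evidence of a dose effect. Over clusters, 897 were higher and 1104 lower (44.8% higher, exact binomial p = 4.05e-06). Among tiles with an authors' difference of at least 25 points, 72 clusters were higher and 63 lower, which was not significant (53.3% higher, exact binomial p = 0.491). So few clusters leave open whether the direction changed. The gene-annotated tile with the largest loss, given to DACT2 but over 5 kb from it (chr6:168343501-168344000), stood at 77.5% and 76.9% in control, 64.3% and 6.67% at 125 mg/dL and 0% and 19.2% at 250 mg/dL. The LINC01785 tile at chr19:22622501-22623000, in an intron of that non-coding gene, stood at 5.33% and 19.9% in control and at 87.9% and 56.0% at 250 mg/dL.

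The third comparison set the doses against each other. The mean at 125 mg/dL lay strictly between those of control and 250 mg/dL in 1380 tiles (67.3%), while 250 mg/dL was in the middle in 328 and control in 315. The share with 125 mg/dL in the middle was 49.9% without 125 mg/dL replicate 1 and 62.7% without 125 mg/dL replicate 2. Control was lowest and 250 mg/dL highest in 618 tiles, and the reverse held in 762. No library of a group overlapped another group in 265 tiles with 125 mg/dL in the middle (116 upwards with dose, 149 downwards), in 42 with control in the middle and in 37 with 250 mg/dL in the middle. Exchangeable libraries, without the selection of tiles for a difference, would give 45.6 tiles for each middle group. The DACT2, STXBP2, BCR and TADA3 tiles lay outside the control range on the same side at both doses.

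**Figure D1:**
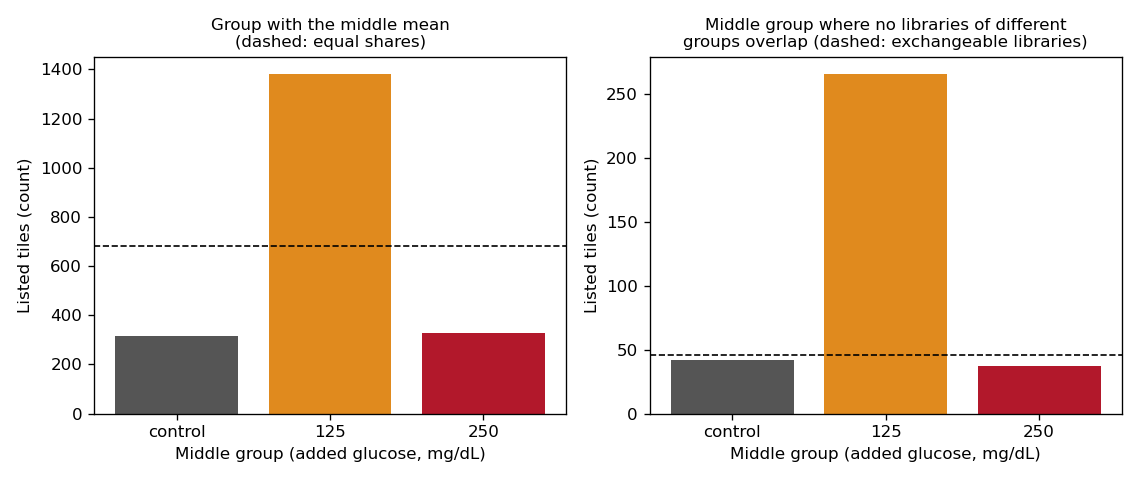
Bars count the listed tiles (vertical axes) by the group in the middle (horizontal axes, added glucose in mg/dL), for group means on the left and, on the right, for tiles in which no libraries of different groups overlap. The 125 mg/dL group is in the middle in 1380 tiles on the left and 265 on the right; dashed lines mark equal shares on the left and the 45.6 tiles given by exchangeable libraries on the right.

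Per cluster the difference at 250 mg/dL was larger than that at 125 mg/dL by a mean of 4.15 points (1620 larger, 362 smaller, sign-flip permutation p = 1e-05, the smallest the resamples can give). Replicates also lay farther apart at 250 mg/dL, by a median of 4.21 points against 3.11 at 125 mg/dL and 3.05 in control. In limma 0 tiles were called between 250 and 125 mg/dL, with 179 at an unadjusted p under 0.05. The shift in size was 2.45 points without 125 mg/dL replicate 1.

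Differences at the 2 doses were correlated across tiles, which are not independent replicates (Pearson r = 0.673, Spearman rho = 0.718), and 84.2% of tiles had both on the same side. Unchanged groups simulated against common controls gave r = 0.497 and 66.6%. With 1 control library for each dose, r was 0.355 and 0.354. The covariance was 81.9 squared points, against 33.8 simulated and 156 simulated with selection of the most different tiles, so it did not exceed the latter. That selection may differ from the authors' unknown test, so the simulation cannot settle whether an excess remains. The simulation with selection gave r = 0.492 and 66.8% on the same side, below the observed values. Both doses lay outside the control range on the same side in 833 tiles, 341 above and 492 below, where independent lists would share 143 and 259; part of that excess may come from the shared controls.

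Library by library, 250 mg/dL replicate 1 stood apart. Its Spearman correlation with the other 5 libraries across tiles was 0.817 to 0.908. On the first principal component, with 45.9% of the variance, it had a loading of 0.74, against 0.22 for 250 mg/dL replicate 2, -0.13 and 0.03 for the 125 mg/dL libraries and -0.50 and -0.36 for the controls. It lay farther from the control mean than replicate 2 did in 59.8% of tiles. Replicate 2 correlated more with the 125 mg/dL libraries (0.949 and 0.929) and control replicate 2 (0.911) than with replicate 1 (0.908). With control replicate 1 it stood at 0.892. All these values rest on tiles chosen for a difference among the same libraries.

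Nitric oxide signalling, which relaxes vessels, was represented by 7 genes and 7 tiles. At 250 mg/dL 2 lay above and 5 below both controls, and at 125 mg/dL 1 lay above, 4 below and 2 within the control range. In NOS3, the endothelial nitric oxide synthase, the tile at chr7:151001501-151002000 lay within the gene and outside CpG islands, shores and shelves. It was labelled promoter, exon and intron, without saying which transcript's promoter is meant. The tile stood at 95.8% ± 1.85 in control, 82.1% ± 2.98 at 125 mg/dL and 64.6% ± 34.8 at 250 mg/dL (SD, n = 2 each). The 250 mg/dL libraries were at 40% and 89.2%, so its mean rests largely on replicate 1 (difference -6.62 points without it and -55.8 without replicate 2), and both 125 mg/dL libraries also lay below both controls. The differences of -13.7 and -31.2 points did not pass limma (adjusted p = 0.764 and 0.204); in the authors' deposited table the difference was 20.3 points and the q-value 0.000296.

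Among the other members, GUCY1B1, a subunit of the nitric oxide receptor, stood at 18.3% ± 1.82 in control and 7.23% ± 5.70 at 250 mg/dL (SD, n = 2), and its difference of -11.0 points was -6.99 without 250 mg/dL replicate 1. The tile given to ASS1, an enzyme of arginine synthesis over 5 kb away, stood at 55.2% ± 1.47 and 32.4% ± 3.38. PRKG1, a cGMP-dependent kinase, was at 2.60% ± 0.218 in control and listed at 0 in all 4 glucose libraries. The CAV1 tile, over 5 kb from the caveolin gene, stood at 50% in 250 mg/dL replicate 1 and at 1.37% to 3.55% in the other 5 libraries. Its authors' difference was 3.65 points, against 24.9 for the unweighted means at 250 mg/dL. If the authors' value is the largest pairwise group difference with weighted libraries, the 50% library had little weight in it. The 24.9 points then rest on that library alone, and the reads behind its 50% are unknown. limma called 0 of the 7 tiles at either dose, over all tiles or adjusted over the list alone, with 1 and 3 at an unadjusted p under 0.05.

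**Figure D2:**
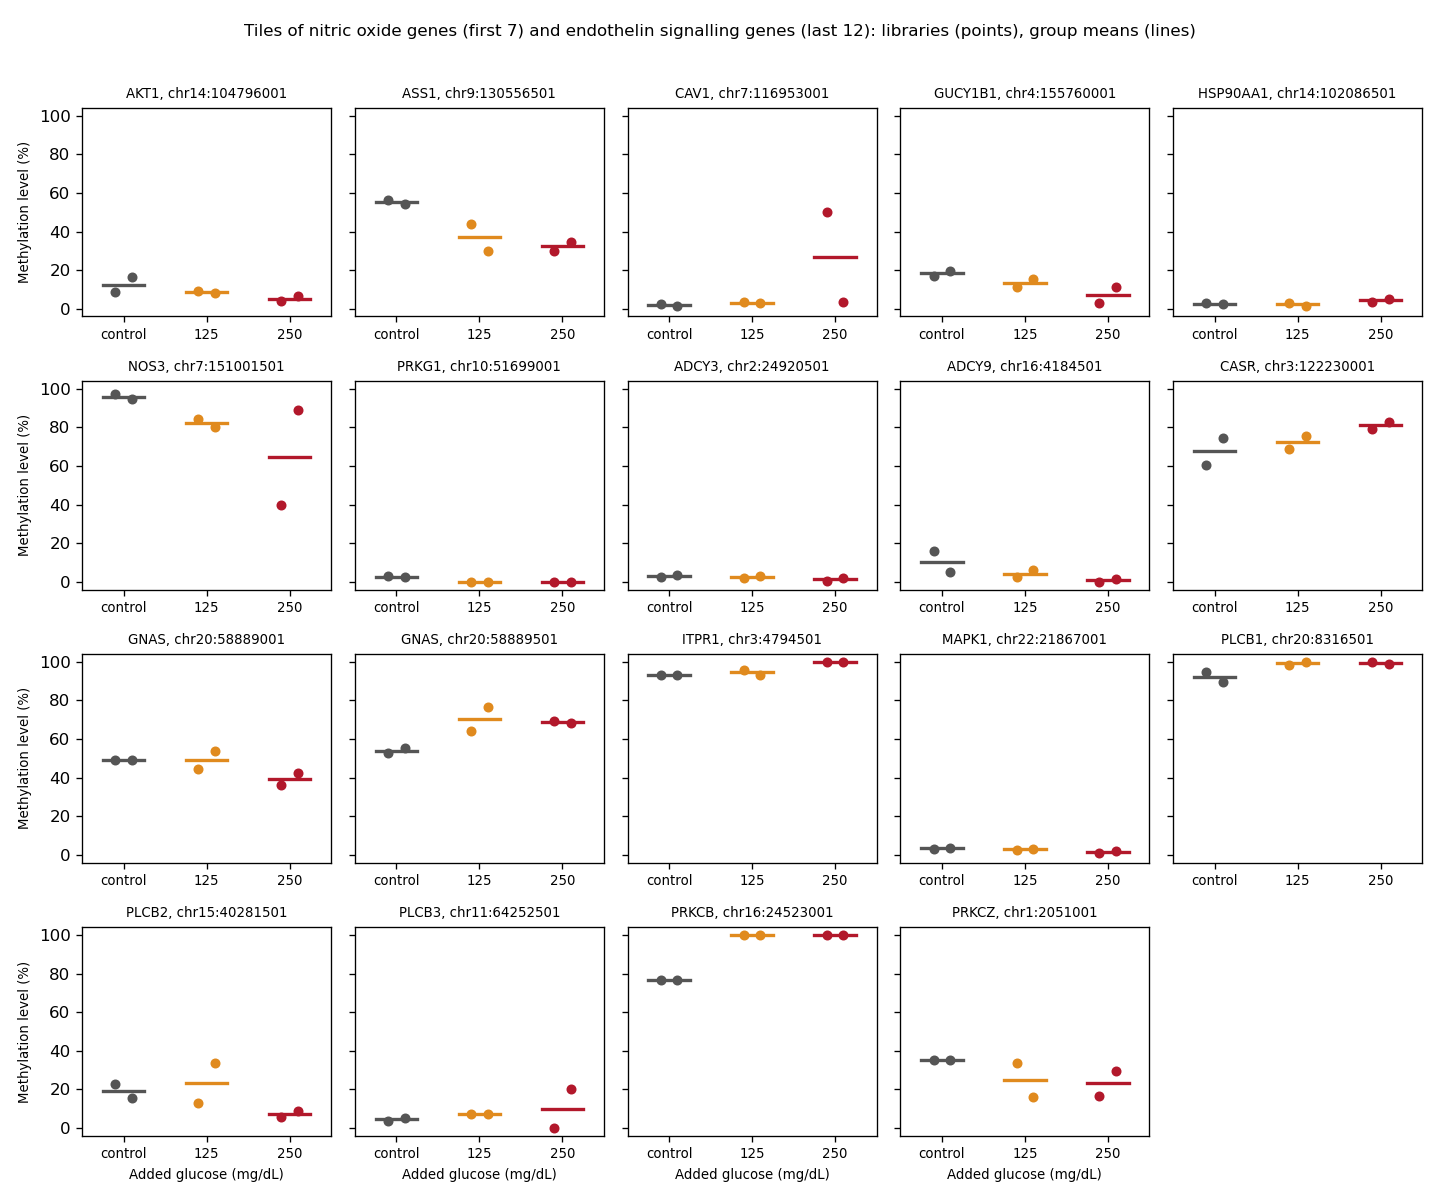
Each panel is 1 tile of the nitric oxide list (first 7) or the endothelin list (last 12), with the methylation level in percent on the vertical axis and the group on the horizontal axis; points are libraries and lines group means. NOS3 at 250 mg/dL is split between 40% and 89.2%, and all 4 glucose libraries of PRKCB are at 100%.

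Endothelin signalling, which constricts vessels, was represented by 11 genes and 12 tiles. At 250 mg/dL 5 tiles lay above, 6 below and 1 within the control range, and at 125 mg/dL 5, 2 and 5. The 2 tiles in GNAS, which encodes a stimulatory G protein subunit, went opposite ways: 54.0% ± 2.02 in control and 68.8% ± 0.568 at 250 mg/dL for chr20:58889501-58890000, and 49.3% ± 0.0631 and 39.2% ± 4.39 for the neighbouring tile at chr20:58889001-58889500 (SD, n = 2). PLCB1, a phospholipase, stood at 92.2% ± 3.66 and 99.4% ± 0.813, a difference of 7.21 points that was 4.62 without control replicate 2. ADCY9, an adenylyl cyclase gene over 5 kb from its tile, stood at 10.4% ± 7.92 and 0.811% ± 1.15; the difference of -9.60 points was -4.0 without control replicate 1 and -15.2 without control replicate 2. limma called PRKCB alone at 250 mg/dL, over all tiles and adjusted over the list alone, and at 125 mg/dL 0 over all tiles and 1 adjusted over the list alone.

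The 16 gene lists gave no comparison past adjustment among 48 (Fisher's exact test, 4 with an unadjusted p under 0.05, smallest adjusted p = 0.388). HOX genes, which set positional identity, had 9 genes on 7 tiles, of which 5 lay above and 2 below both controls at 250 mg/dL. In HOXB3 the tile at chr17:48577001-48577500 stood at 20% ± 4.71 in control and 52.2% ± 7.80 at 250 mg/dL (SD, n = 2). Clustered protocadherins had 7 genes but only 2 tiles, both below, with PCDHGA1 at 53.0% ± 0.839 and 35.9% ± 9.83 in the first (difference -17.1 points, -10.1 without 250 mg/dL replicate 1). Imprinted genes had 14 tiles, 5 above and 5 below; both MEG3 tiles lay above the controls at 250 mg/dL, by 13.9 and 17.9 points. The first difference was 3.53 points without 250 mg/dL replicate 1 and 24.3 without replicate 2, and the second 7.71 without control replicate 1 and 28.1 without control replicate 2. For HOX and imprinted genes limma called 0 tiles over all tiles at 250 mg/dL and 1 adjusted over the list alone; for protocadherins it called 0 either way.

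Insulin signalling had 10 tiles, 5 above and 3 below at 250 mg/dL, among them FOXO3, a transcription factor restrained by insulin, at 7.38% ± 1.37 in control and 18.9% ± 10.7 at 250 mg/dL (SD, n = 2). Its 250 mg/dL libraries stood at 26.4% and 11.3%, and the difference of 11.5 points was 3.92 without replicate 1 and 19.1 without replicate 2. The extracellular matrix list had 13 tiles, 6 above and 5 below, and endothelial identity and VEGF signalling had 9, 4 above and 4 below. A tile in FLI1, an endothelial transcription factor, stood at 63.9% ± 19.6 in control and 84.4% ± 5.73 at 250 mg/dL (SD, n = 2). Its difference of 20.5 points was 34.4 without control replicate 1 and 6.63 without control replicate 2. DNA methylation and chromatin enzymes had 8 tiles, 3 above and 3 below, with DNMT3B, a DNA methyltransferase, at 6.94% ± 1.23 and 12.5% ± 1.04. Glucose transport and glycolysis had 4 tiles, 1 above and 2 below. In these 5 lists limma called 0 tiles at 250 mg/dL, over all tiles or adjusted over the list alone.

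The Notch and TGF-beta list had 9 tiles, 2 above and 4 below at 250 mg/dL, with HES1, a Notch target, at 2.92% ± 3.18 in control and 12.2% ± 1.22 (SD, n = 2). The polyol and glycation list had 2, with HAGH above by 10.3 points (6.29 without 250 mg/dL replicate 1) and SORD, sorbitol dehydrogenase, below by a difference of -6.56 points. Markers of smooth muscle, fibroblasts and blood cells had 2 tiles, PDGFRA, over 5 kb from its tile, and ITGAM, both above. limma called 0 tiles of these lists over all tiles, and adjusted over the list alone 1, 2 and 2 at 250 mg/dL. Adjustment over lists of 2 tiles is slight, and the tiles were already chosen for a difference. Of all 2051 tiles, 535 had an unadjusted limma p under 0.05 at 250 mg/dL, so these calls say little about the lists. Oxidative stress had 2 tiles, KEAP1 above and TXNRD1 below, coagulation 2, both below, and inflammation 1, TRAF2, above; limma called 0 of these at 250 mg/dL either way. At 125 mg/dL limma called 0 tiles of any list over all tiles, and adjusted over the list alone 1 for endothelin, 2 for polyol and glycation, 1 for inflammation and 0 for the other 13.

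TAFA5, PTPRN2 and SOX8 had 6 tiles each, of which 1, 0 and 4 lay over 5 kb from the gene, with 1, 3 and 1 above and 3, 3 and 4 below both controls at 250 mg/dL. Of 2001 clusters 1952 were single tiles, 48 held 2 and 1 held 3. The last, at AQP11, a water channel gene, had a lower mean in all 3 tiles at 250 mg/dL, with differences of -15.2, -2.08 and -5.17 points, none of which passed limma. The first of these tiles was not outside the control range, and its difference was -3.66 points without 250 mg/dL replicate 1 and -26.8 without replicate 2; that of the third was -3.43 points without control replicate 2.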

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

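All tests of technical explanations in this part were chosen after the results had been seen. In 42 tiles both libraries of one dose lay above both controls and both libraries of the other dose below. Exchangeable libraries would give 45.6 such tiles, a value that leaves out the selection of tiles for a difference. The share of such tiles, 2.05% against 2.22% by chance, was 9.70% without 125 mg/dL replicate 1 and 2.49% without 250 mg/dL replicate 1, where chance is 6.67%. Among the named tiles this held for RILPL1 and MIR3908 (chr12:123534501-123535000), with 12.2 points at 125 mg/dL (5.39 without control replicate 1, 19.02 without control replicate 2) and -53.3 at 250 mg/dL. It held for TRAF2, with -30.1 and 17.8 points, and for FOXO3, with -1.91 and 11.5 points. Without 250 mg/dL replicate 1 the differences at 250 mg/dL were 8.61 points for TRAF2 and 3.92 for FOXO3, without replicate 2 they were 26.9 and 19.1, and that of FOXO3 at 125 mg/dL was -0.940 without control replicate 1 and -2.88 without control replicate 2. It also held for a tile over 5 kb from FRYL, the gene it was given to (chr4:49634001-49634500), with -3.05 points at 125 mg/dL (-0.749 without 125 mg/dL replicate 1, -5.36 without replicate 2) and 4.89 at 250 mg/dL. Over all tiles limma called none of these 4 tiles against control at either dose, and called 0 tiles between the doses, with 179 at an unadjusted p under 0.05. TRAF2, the only tile of the inflammation list, passed at 125 mg/dL when adjusted over the list alone.

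The order of the groups, with 125 mg/dL in the middle in 67.3% of tiles, was weighed against technical explanations. Wider scatter of the 250 mg/dL libraries alone would put control and 125 mg/dL at the other end equally often, but control was there in 81.4% of such tiles (95% Wilson interval 79.5 to 83.2). Selection acting equally on the 3 groups would give 33.3%, and the lowest share over the 8 sets of single libraries was 44.7% (42.5 to 46.8). Both intervals treat tiles as independent, although all share 6 libraries. Unequal depth among groups, any batch that follows dose, and selection that favoured an order by dose stay open. Depth and the authors' differential test are unknown, and the labels give no batch. A response to glucose is a hypothesis beside these explanations.

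The distance of 250 mg/dL replicate 1 from the other libraries was also weighed. Incomplete bisulfite conversion would raise tiles with little methylation elsewhere, and replicate 1 lay above replicate 2 in 48.0% of them (Wilson interval 44.4 to 51.7). That interval includes 50%, so some incomplete conversion stays open. A looser bound of 60%, tried after the value was seen and not kept, would have excluded it. Incomplete conversion raises levels only, and over all listed tiles replicate 1 lay above the control mean in 46.0%, against 43.5% for replicate 2. These values argue against conversion as the whole cause of the distance, which ran in both directions. In each listed mitochondrial tile, however, replicate 1 had the highest level of all libraries. It stood there at 3.55%, 3.76% and 24.0%, against 2.38%, 2.86% and 0.279% in replicate 2. Incomplete conversion could also give this, so it stays open as a part of the distance. Fewer reads would leave more tiles at exactly 0 or 100%, and replicate 1 had 171, against 130 in the next library. That count had been seen when the test was set and also depends on which tiles were listed, so fewer reads may be a cause without being established, and a stronger response in that culture was not tested.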

How the results depend on the processing

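The limma settings on logit and arcsine square root scales, without the trend and on autosomes, and all settings of the shares fully separated in dose order or on opposite sides, were chosen after seeing the data. The majority of lower clusters kept its direction and its side of the threshold at a q-value under 0.01, on autosomes, with gaps of 100 or 10000 bp and without any 1 library. With an authors' difference of at least 25 points, 63 clusters were higher and 72 lower at 125 mg/dL (46.7% higher, exact binomial p = 0.491). At 250 mg/dL 72 were higher and 63 lower (53.3% higher, exact binomial p = 0.491). So few clusters leave open whether the majority changed, and no cause was tested. Clusters in 1 direction numbered 25 at 125 mg/dL and 23 at 250 mg/dL with at least 2 tiles, and 0 at 250 mg/dL with gaps of at most 100 bp or at least 5 tiles, where fewer tiles qualify. limma at 125 mg/dL called 3 tiles on the logit scale and 2 on the arcsine square root scale, and at 250 mg/dL 5 on the latter; smallest adjusted p-values over all settings ran from 0.0242 to 0.989 at 125 mg/dL and from 0.0206 to 0.225 at 250 mg/dL. With the replicate number as a replicate block limma called 0 tiles at both doses, with 155 and 435 at an unadjusted p under 0.05. Deviations of same-numbered libraries correlated at 0.024, 0.023 and -0.072. These values show no sign of pairing across tiles but cannot exclude it, since the labels do not say how the cultures were related.

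With each library left out, clusters higher ranged from 41.9% to 44.9% at 125 mg/dL and from 43.5% to 45.8% at 250 mg/dL, and tiles outside the control range from 49.0% to 78.1% and from 78.5% to 90.8%. The lower ends come from leaving out a library of the other dose, with a chance of 33.3%. With 1 library against 2, where chance is 66.7%, the ranges were 71.9% to 78.1% and 86.4% to 90.8%. All chance values in this paragraph leave out the selection of tiles for a difference. The share on the same side ranged from 77.8% to 85.0%, the correlation from 0.569 to 0.759, the shift in size from 2.45 to 6.04 points and the share with 125 mg/dL in the middle from 49.9% to 64.3%. The share fully separated in dose order, 12.9% with all libraries and 2.22% by chance, ranged from 20.4% to 33.3%, and the share on opposite sides at the 2 doses, 2.05% with all libraries, from 2.49% to 9.70%, where chance is 6.67% for both. limma calls ranged from 0 to 0 at 125 mg/dL and from 0 to 128 at 250 mg/dL, the lone library being assumed to vary like the others. Among 1184 differences of named tiles with a library left out, 1180 moved by no more than the pooled replicate SD, a test that can hardly fail with 2 libraries. Not run were positions matched within 1 or 100 bp, since tiles share 1 grid, and a coverage of at least 20, since no coverage was used here; unknown depth limits every value.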

Other observations

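No explanation is offered for the observations in this part, and the division of tiles by level was chosen after the data had been seen. Tiles were divided into 6 bins by control level, and the share with a higher mean at 250 mg/dL ran from 35.6% in the bin of 5 to 20% to 59.6% in the bin up to 5%. Binned on the 125 mg/dL mean instead, those bins gave 39.3% and 45.3%, so the share in the lowest bin depends on the group used for binning. The bin above 80% gave 41.1% with control binning and 54.9% with 125 mg/dL binning.

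Mitochondrial DNA held 3 listed tiles. The tile at 7001 to 7500 stood at 24.0% in 250 mg/dL replicate 1 and at 0.279% in replicate 2, with 1.07% to 5.04% in the other 4 libraries. Its authors' difference was 12.2 points and its q-value 1.80e-26. The other 2 tiles stayed between 0.244% and 3.76% in all 6 libraries. KEAP1, a sensor of oxidative stress, stood at 53.0% ± 12.6 in control and 76.7% ± 8.46 at 250 mg/dL (SD, n = 2), and limma did not call it (adjusted p = 0.189). The difference of 23.7 points was 14.8 without control replicate 1.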
